A study of Mus musculus with 20 samples.

How the data were processed

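Bulk RNA sequencing of poly(A) RNA was analysed from mouse breast tumours grown as allografts. The tumours were MDA594, which is sensitive to PARP inhibitors, and the olaparib-resistant MDA594OR1 and MDA594OR2, named OR1 and OR2 here, each untreated or treated with olaparib. Per the labels, RNA was extracted with RNeasy Mini columns and libraries were made with the KAPA stranded mRNA kit. The processing notes name STAR 2.7.10a, RSEM 1.3.1, limma without a version, and the mouse build GRCm39; the annotation, its release and the authors' filter on genes are not stated in the sources used here. The deposited values are log2 counts per M reads (CPM) made by the authors. In each of the 20 libraries, the antilogs took evenly spaced steps that recovered whole reads at a tolerance of 0.01 reads, and they matched log2 of reads plus 0.5 per M of a scaled library size. Gene symbols and Ensembl identifiers are given as deposited. No positions are printed, since the gene table at hand is on GRCm38; it was used only for the order of neighbouring genes.

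Groups were taken from the titles and treatment labels. There were 6 groups and 19 libraries with a group. For 1 more library, the title says control and the treatment label says treated, so it entered no comparison. In 5 cases, 2 libraries shared the last code of the title, which was taken to mean tumours from 1 host animal although the labels do not spell this out. The 19 libraries carry 14 codes, and both untreated OR2 libraries carry the same code. Library names fall into 2 series, and the titles carry a number that also splits the libraries; both were treated as possible batches.

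The table held 16411 genes. Genes were kept when their log2 CPM exceeded 0 in at least 2 libraries, which removed 81 and left 16330. The deposited values were modelled in R 4.3.3 with limma 3.58.1. The model had 1 mean per group, a correlation between libraries with the same code (0.404), 13 residual degrees of freedom and moderated variances with a mean trend. Each comparison was a contrast of group means, and the responses of OR1 and OR2 were also compared with that of MDA594 as interaction contrasts. Untreated OR1 and untreated OR2 enter their treatment response and their comparison with MDA594 with opposite signs, so these are not independent. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. All p-values measure the spread between these libraries. Because several tumours shared an animal, and 1 group had a single code, they do not measure the spread over a wider set of animals.

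The design, the comparisons, 35 gene lists and the alternatives were fixed before the data were examined. The lists held 692 entries and 678 distinct genes, of which 584 were tested, and a list needed at least 5 tested members. Some genes belong to more than 1 list. Each list was tested with the preset camera method of limma (correlation 0.01) on the moderated statistics, which compares the list with all other genes, and list p-values were adjusted over the lists of a comparison. The same lists were tested with a correlation estimated from the residuals, and with fry, which tests whether the members of a list move on balance in 1 direction. The test with an estimated correlation refitted the values without the correlation between libraries of a code and without the mean trend. It thus differs from the preset test in these points too. Members of a list were also adjusted over the list alone. A list score is the mean log2 CPM of its tested members in a library.

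Named genes followed a fixed rule. Up to 8 genes with the largest rise and 8 with the largest fall were named per comparison, among those past the threshold, with a mean of at least 1 in the higher group and no overlap between the libraries of the groups. To these were added the 4 members with the smallest p of each list past the threshold, and a fixed set of genes of the study's subject, of which 3 were absent from the table. Genes named outside this rule are said to be so. For Fads2b and Slc34a2, whose libraries in 1 group had at most 7 reads, recovered reads are given in place of a fold.

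The pipeline was tested on simulated data with the same groups and codes, in which 100 genes changed 2-fold and 100 changed 4-fold. In the 7 comparisons, 17 to 56 of the genes changed 2-fold and 76 to 91 of those changed 4-fold were called, and false calls made up 3.55% to 8.82% of calls. Without the correlation between libraries of a code, that share was 14.9% to 24.9%. Libraries of a code were simulated with the fitted correlation, so leaving it out was bound to raise this share. Each comparison was simulated once, genes varied independently of one another, and genes with a low mean were not changed. These shares thus need not hold for the real data, where genes are correlated.

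Alternatives changed the filter, the added constant, the normalisation, the handling of shared codes, library-name series and title numbers, the variance moderation, the threshold and the libraries included, each 1 at a time. Voom weights on the recovered reads, and a fit without the MDA594 control code that stood apart, were added after the data had been seen. Raw reads were not analysed here, so alignment and counting could not be varied. Cell types were not measured directly; marker lists of cell types are read here only as sums over transcripts.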

Results

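The data were 20 transcriptomes of mouse breast tumours carried as allografts, meaning pieces of a mouse tumour grown in other mice. MDA594 responds to olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2, and OR1 and OR2 are olaparib-resistant. Untreated MDA594 had 4 libraries of 48.7 to 89.2 M reads, and treated MDA594 had 3 of 63.0 to 118 M. Untreated OR1 had 3 libraries of 44.2 to 87.7 M, and treated OR1 had 4 of 36.8 to 77.8 M. Untreated OR2 had 2 libraries of 74.9 and 77.6 M, both with the same host code, and treated OR2 had 3 of 94.1 to 116 M. The library with no group had 49.2 M reads. Changes are log2 differences of group means from limma, with standard errors (SE). Group values are log2 counts per M reads (CPM) with standard deviations (SD). The n given with an SD counts libraries, not host codes. Untreated MDA594 had 3 host codes, and treated MDA594 and untreated OR1 had 2 each. Treated OR1 and treated OR2 had 3 each. Where libraries share a code, the SD can thus understate the spread between animals.

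The first comparison asked what olaparib changed in the sensitive tumours. Genes induced by type I interferon were higher with treatment, with positive changes for 37 of 37 tested genes and a median of 1.82. Isg15, a ubiquitin-like protein, changed by 2.50 (SE 0.52), Oas1a, a sensor of double-stranded RNA, by 2.56 (SE 0.59), and Ifit2 by 1.77 (SE 0.41). Of the 37, 34 passed when adjusted over the list alone and 0 passed over all genes, where Isg15 had an adjusted p of 0.0681. Among chemokines that recruit lymphocytes, 12 of 12 were higher with a median of 1.59. Cxcl10 (ENSMUSG00000034855.14), a ligand of CXCR3 on T and NK cells, rose by 2.85 (SE 0.53, adjusted p = 0.0495 over all genes), from 3.06 ± 1.12 (SD, n = 4) to 6.06 ± 0.45 (SD, n = 3). Cxcl9 at 3.15 (SE 1.08) and Cxcl16 at 1.39 (SE 0.38) were among 5 chemokines that passed when adjusted over the list alone, against 1 over all genes. Those 5 became 11 without MDA594_control 1, 3 without MDA594_control 2 or MDA594_olaparib 2, and 2 without MDA594_olaparib 3. In the list of cytosolic nucleic acid sensing the median was 0.25 and 6 of 21 genes passed over the list alone, including Zbp1 at 1.66 (SE 0.46) and Ifi204 at 1.76 (SE 0.49), and 0 passed over all genes. The sensor Cgas (0.59, adjusted p = 0.288) and its adaptor Sting1 (0.12, adjusted p = 0.853) did not pass.

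**Figure D1:**
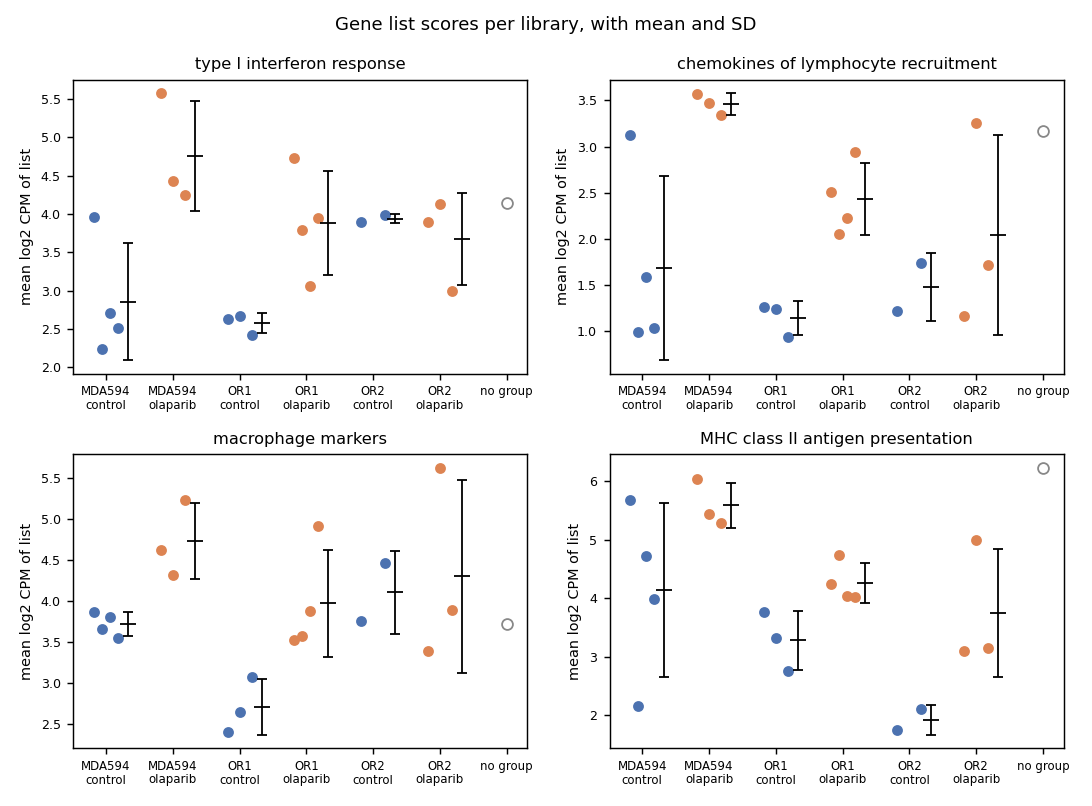
Scores of gene lists in each library, as mean log2 CPM of the list's tested genes (vertical axis), by tumour line and treatment (horizontal axis); points are libraries, black bars are the mean and SD, and the open grey point is the library with no group. The interferon score was 2.86 ± 0.77 (SD, n = 4) in untreated and 4.75 ± 0.72 (SD, n = 3) in treated MDA594, 2.57 ± 0.13 (SD, n = 3) and 3.88 ± 0.69 (SD, n = 4) in OR1, and 3.94 ± 0.06 (SD, n = 2) and 3.67 ± 0.60 (SD, n = 3) in OR2.

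The camera test of limma gave an adjusted p of 1.31e-26 for the interferon list, 8.89e-07 for chemokines and 0.0013 for nucleic acid sensing. None of these held with an estimated correlation, with an adjusted p of 0.362 for each. With fry each had an adjusted p of 0.0495, as did dendritic cell markers and the unfolded protein response. In this comparison, 20 of 35 lists were higher and 3 lower with the preset correlation, 0 with an estimated correlation and 5 with fry. For the interferon list the adjusted p ran from 1.08e-39 to 0.362 over 24 alternatives and the median from 1.53 to 2.36; the camera call was lost in none of the fits without 1 library. Within the library-name series that holds all treated MDA594 libraries the median was 2.21, and with the title number in the model it was 2.36.

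Markers of host cells moved with these lists. Macrophage markers had a median of 1.11 (adjusted p = 2.36e-06; adjusted p = 0.484 with an estimated correlation), and 9 of 21 passed over the list alone and 0 over all genes, including Cd68 at 1.47 (SE 0.39) and C1qa at 1.62 (SE 0.47). That count of 9 was 3 without MDA594_control 2. Class II antigen presentation had a median of 1.57 (adjusted p = 4.69e-05; adjusted p = 0.484 with an estimated correlation), led by Ctss, a lysosomal protease, at 1.52 (SE 0.52) and H2-Ab1 at 2.07 (SE 0.76). Its 6 members past the threshold over the list alone became 0 without MDA594_control 2, MDA594_control 4 or any 1 of the 3 treated libraries, and 10 without MDA594_control 1, and its median was 0.83 without MDA594_control 2. T cell markers had a median of 1.45 and NK cell markers of 1.38, with 20 of 20 and 10 of 10 genes positive and 0 past the threshold over either list or over all genes (adjusted p = 3.24e-05 and 0.00124; adjusted p = 0.484 for both with an estimated correlation). Without MDA594_control 2 these medians were 0.61 and 0.75 and neither list was called. The NK list was not called within 1 library-name series (1.05) or with the title number in the model (1.34). Ligands of NK cell receptors had a median of 0.31 (adjusted p = 0.01; adjusted p = 0.445 with an estimated correlation). Cd48 at 1.64 (SE 0.49), the costimulator Cd80 at 1.97 (SE 0.66) and Raet1d, a ligand of the activating receptor NKG2D, at 1.35 (SE 0.48) passed over that list alone and 0 over all genes. The ligand list was not called without MDA594_control 2 (0.37). Neutrophil markers were lower, with a median of -0.54 (adjusted p = 0.0134; adjusted p = 0.484 with an estimated correlation), and the call was lost without MDA594_control 3, at -0.29. Fibroblast markers had a median of 0.81 (adjusted p = 0.00801) and endothelial markers of 0.72 (adjusted p = 0.0124), each at adjusted p = 0.579 with an estimated correlation. Neither was called within 1 library-name series (0.36 and 0.34), with the title number in the model (0.11 and 0.13) or without MDA594_olaparib 3 (0.30 and 0.37), and endothelial markers were not called without MDA594_control 2 (0.54). Mitochondrially encoded genes had a median of -0.61 (adjusted p = 0.0219; adjusted p = 0.564 with an estimated correlation), and were not called with quantile normalisation (-0.19), within 1 library-name series (-0.68) or without MDA594_control 1 (-0.52) or MDA594_olaparib 1 (-0.47). Skeletal muscle markers had a median of 4.03, but their score was -0.25 ± 5.53 (SD, n = 3) in treated tumours, and without MDA594_olaparib 3 the median was -0.38 and not called (adjusted p = 2.34e-05 with all libraries; adjusted p = 0.509 with an estimated correlation).

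In the same tumours, 8 chaperones and other genes of the unfolded protein response were higher over the list alone and 1 was lower. Creld2, an endoplasmic reticulum protein, rose by 0.99 (SE 0.18, adjusted p = 0.0495 over all genes), the only 1 of the 8 past that threshold, and Hspa5, the main chaperone there, was higher by 0.67 (SE 0.21), while the kinase-like Trib3 was lower at -0.60 (SE 0.24). The list's adjusted p was 2.15e-05, and adjusted p = 0.362 with an estimated correlation; the 8 genes became 4 without MDA594_control 2 and 1 without MDA594_olaparib 3. Mitotic and S phase genes had a median of 0.38 (adjusted p = 4.49e-06; adjusted p = 0.484 with an estimated correlation), with Cdc6 and Pcna, which act in DNA replication, among 4 past the threshold over the list alone and 0 over all genes. Hypoxia and glycolysis genes were lower, with a median of -0.64 (adjusted p = 3.25e-05; adjusted p = 0.484 with an estimated correlation). Bnip3 at -1.13 (SE 0.25) and the glucose transporter Slc2a1 at -0.78 (SE 0.26) were among 5 lower over the list alone and 0 over all genes. Those 5 became 1 without MDA594_control 2 or MDA594_olaparib 2, 3 without MDA594_olaparib 1 and 0 without MDA594_olaparib 3. Within the library-name series of the treated libraries the hypoxia median was -0.37 and not past the threshold.

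Over all genes, 9 rose and 11 fell with olaparib in MDA594, with adjusted p of 0.0495 or 0.0497. The largest rise was in Clec7a (ENSMUSG00000079293.13), a fungal glucan receptor of myeloid cells, at 3.50 (SE 0.66), from 2.74 ± 1.24 (SD, n = 4) to 6.28 ± 0.37 (SD, n = 3), followed by Ms4a4c at 3.11 (SE 0.59). Mfsd12, Cdr2, Nectin3 and Lactb also rose, by 0.94 to 1.42. Falls included Ccdc60 at -2.86 (SE 0.50), Fn3k at -1.93 (SE 0.33), Mettl27, Selenbp1, Hdac11 and Lurap1. Dbp (ENSMUSG00000059824.13), a transcription factor driven by the circadian clock, fell by 1.43 (SE 0.25), and Rora, a nuclear receptor of the same clock, fell by 1.19 (SE 0.19). At an unadjusted threshold of 0.05 there were 2740 genes against 816 by chance, and voom called 0 higher and 0 lower. The counts were 251 and 138 without MDA594_control 1, 18 and 22 without MDA594_control 3, 0 and 6 without MDA594_control 4, and 3 and 15 without MDA594_olaparib 1. They were 0 and 0 without MDA594_control 2, MDA594_olaparib 2 or MDA594_olaparib 3. With the library-name series in the model they were 54 and 57, within 1 series 2857 and 2363, and with the title number in the model 1764 and 1359. In the latter fits the estimated correlation between libraries of a code was negative (-0.298 and -0.127), which narrows the standard errors. Both fits rest on MDA594_control 3 and MDA594_control 4 as controls, which share 1 code.

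The second comparison asked how OR1 tumours responded to olaparib. Interferon-induced genes were again higher in 37 of 37, with a median of 1.42; Ifit3 changed by 2.48 (SE 0.64), Ifi27l2a by 2.31 (SE 0.58) and Irf7, a transcription factor of the pathway, by 2.12 (SE 0.64). Of these, 19 passed over the list alone and 0 over all genes. Chemokines had a median of 1.14, with Ccl5 at 1.90 (SE 0.42) and Cxcl10 at 1.67 (SE 0.53) among 6 past the threshold over the list alone. Macrophage markers had a median of 1.28, with Cd68 at 1.41 (SE 0.39) and C1qc at 1.43 (SE 0.44) among 5, and no chemokine or macrophage marker passed over all genes. NF-kB and inflammatory genes had a median of 1.09, led by the adhesion molecule Icam1 at 1.71 (SE 0.47), the 1 gene past the threshold over the list alone. Genes of mitosis and S phase were lower in 30 of 30, with a median of -0.35, and homologous recombination genes had a median of -0.24, with 0 genes of either past the threshold over its list. The NF-kB median was 0.58 without OR1_control 3.

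Drug efflux transporters were higher with olaparib in OR1 in 9 of 9 genes, with a median of 0.42. The P-glycoprotein genes Abcb1a and Abcb1b, whose product exports olaparib, changed by 1.46 (SE 0.48) and 1.22 (SE 0.44), and each missed the threshold over the list alone at 0.0595. In MDA594 the same list was not called (median 0.12, adjusted p = 0.238), and Abcb1b changed by 1.44 (SE 0.44), with p of 0.0421 adjusted over the list alone and 0.129 over all genes. The difference between the OR1 and MDA594 responses of this list was 0.30 (adjusted p = 0.221).

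**Figure D2:**
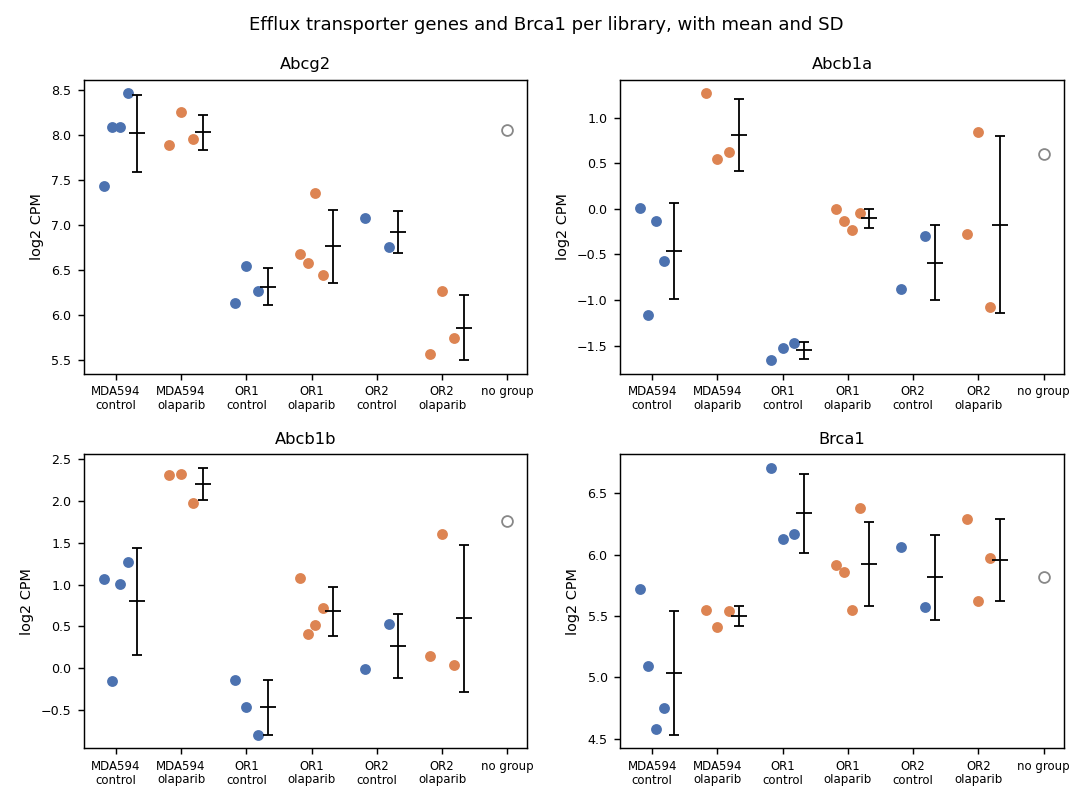
Log2 CPM of efflux transporter genes and Brca1 in each library (vertical axis) by tumour line and treatment (horizontal axis); points are libraries, black bars are the mean and SD, and the open grey point is the library with no group. Abcg2 was 8.01 ± 0.43 (SD, n = 4) in untreated MDA594 and 6.31 ± 0.21 (SD, n = 3) in untreated OR1.

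With the camera test of limma in OR1, adjusted p was 3.45e-30 for interferon, 1.49e-09 for chemokines, 4.35e-16 for macrophage markers, 3.13e-08 for NF-kB genes, 3.81e-13 for mitosis and S phase, 1.23e-05 for homologous recombination and 4.38e-05 for efflux. Each had adjusted p = 0.231 with an estimated correlation. Of 35 lists, 23 were higher and 7 lower, 0 with an estimated correlation and 0 with fry. The interferon median was 1.08 within 1 library-name series and 1.02 with the title number in the model. OR1_control 3 is the only untreated OR1 library in that series, so all values within it rest on 1 control library. Neutrophil markers had a median of 1.02 (adjusted p = 9.74e-06; adjusted p = 0.231 with an estimated correlation), T cell markers of 1.15 (adjusted p = 4.21e-06; adjusted p = 0.316 with an estimated correlation), NK cell markers of 1.17 (adjusted p = 3.83e-04; adjusted p = 0.349 with an estimated correlation), and muscle markers of -2.40 (adjusted p = 0.00166; adjusted p = 0.468 with an estimated correlation). Within 1 library-name series muscle markers were not called (-0.97), and their median was -1.42 without OR1_control 1. The NK cell median was 0.72 without OR1_control 3. Fibroblast markers had a median of 0.76 (adjusted p = 3.11e-04; adjusted p = 0.37 with an estimated correlation), endothelial markers of 0.45 (adjusted p = 0.00424; adjusted p = 0.468 with an estimated correlation), mitochondrially encoded genes of 0.72 (adjusted p = 9.12e-05; adjusted p = 0.316 with an estimated correlation) and red cell genes of -2.09 (adjusted p = 1.76e-05; adjusted p = 0.242 with an estimated correlation). None of these was called within 1 library-name series (0.29, 0.34, 0.18 and -0.59). Without OR1_olaparib 4 fibroblast (0.05) and endothelial markers (0.13) were not called, nor were endothelial markers without OR1_control 1 (0.19), and the mitochondrial median was 0.43 without OR1_olaparib 1. The 19 interferon genes became 10 without OR1_control 1, 0 without OR1_control 3, OR1_olaparib 1 or OR1_olaparib 4, 1 without OR1_olaparib 2 and 29 without OR1_olaparib 3. The 6 chemokines became 2 without OR1_control 2, 0 without OR1_control 3 and 1 without OR1_olaparib 4, and the 5 macrophage markers became 12 without OR1_olaparib 1 and 0 without OR1_olaparib 2 or OR1_olaparib 4. Over all genes, limma called 0 higher and 0 lower (smallest adjusted p 0.705), 959 had an unadjusted p under the threshold against 816 by chance, and voom called 0. Without OR1_olaparib 2 the count was 1 higher. In a fit of only the groups compared, limma called 148 genes.

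The third comparison asked how OR2 tumours responded. Class II antigen presentation genes were higher in 11 of 11, with a median of 1.92; the peptide loading factor H2-DMb1 changed by 1.92 (SE 0.61), H2-Eb1 by 2.73 (SE 0.96) and the invariant chain Cd74 by 2.60 (SE 0.96). Dendritic cell markers had a median of 1.12, led by the actin bundler Fscn1 at 2.67 (SE 0.55) and the chemokine Ccl22 at 3.63 (SE 1.20), and the median was 0.69 without OR2_olaparib 2. T cell markers were higher in 19 of 20, with a median of 1.26 (adjusted p = 1.17e-04; adjusted p = 0.986 with an estimated correlation) and 0 past the threshold over the list alone, and were not called without OR2_control 1 (0.71) or OR2_olaparib 2 (0.51). The milk protein genes Csn1s1 at -4.24 (SE 0.94) and Csn2 at -5.31 (SE 1.60) were lower over their list alone, as were 5 genes of red cells, among them Hba-a2 at -3.17 (SE 0.98) and Hbb-bt at -3.58 (SE 1.12). Hypoxia and glycolysis genes were lower in 18 of 19, with a median of -0.57 and 0 past the threshold over the list alone, and neutrophil markers had a median of -1.65, which was -0.95 without OR2_control 1 and -0.96 without OR2_olaparib 1. Interferon-induced genes had a median of -0.29, with 6 of 37 positive, and the list was not called (adjusted p = 0.174). Isg15 changed by -0.59 and Cxcl10 by 0.11.

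The camera test of limma gave adjusted p of 9.12e-08 for class II (adjusted p = 0.46 with an estimated correlation) and 4.20e-06 for dendritic cell markers (adjusted p = 0.358 with an estimated correlation). For milk genes it was 0.0015, for hypoxia 3.03e-08 and for neutrophil markers 7.39e-06, each at adjusted p = 0.358 with an estimated correlation, and for red cell genes 1.53e-06 (adjusted p = 0.459 with an estimated correlation). Of 35 lists, 5 were higher and 5 lower, 0 with an estimated correlation and 0 with fry. The other 3 were mitotic and S phase genes at 0.25 (adjusted p = 1.17e-04; adjusted p = 0.986 with an estimated correlation), 53BP1 and end joining genes at 0.21 (adjusted p = 0.00193; adjusted p = 0.358 with an estimated correlation) and NF-kB genes at -0.48 (adjusted p = 0.0377; adjusted p = 0.986 with an estimated correlation). Mitotic genes were not called without OR2_control 2 (0.15) or OR2_olaparib 3 (0.14), 53BP1 genes without OR2_control 2 (0.22) or OR2_olaparib 1 (0.22), and NF-kB genes without OR2_control 1 (-0.06) or OR2_olaparib 1 (-0.14). The NF-kB median was -0.81 without OR2_control 2, and the mitotic and 53BP1 medians were 0.42 and 0.32 without OR2_olaparib 2. Within 1 library-name series the class II median was 2.17 and the hypoxia median -0.55. Of the class II genes, 5 passed over the list alone and 0 over all genes; the 5 became 0 without OR2_control 1 or OR2_olaparib 2 and 1 without OR2_control 2. The red cell list was not called without OR2_control 2 (-2.63) and the milk list, at -0.74 with all libraries, was not called without it either (-0.79). The milk median was -1.11 without OR2_olaparib 1, -1.28 without OR2_olaparib 2 and -0.34 without OR2_olaparib 3; the 5 red cell genes became 0 without OR2_control 2 or OR2_olaparib 1. Over all genes limma called 0 higher and 0 lower, with 1084 under the unadjusted threshold against 816 by chance, and voom called 0. The counts were 64 and 38 without OR2_control 2, 0 and 2 without OR2_olaparib 2, 146 and 217 within 1 library-name series and 35 and 40 with the title number in the model. Both untreated OR2 libraries share a host code, so untreated OR2 has no measured spread between animals. The same libraries enter the fifth comparison with the opposite sign, where class II genes had a median of -2.76. Opposite changes in these comparisons are thus not independent. A deviation of that 1 animal cannot be told apart from a response to olaparib or a trait of the line.

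The fourth comparison asked how untreated OR1 differed from untreated MDA594. The drug efflux transporter Abcg2 (ENSMUSG00000029802.14) was lower in OR1 at -1.66 (SE 0.29, adjusted p = 0.0311), from 8.01 ± 0.43 (SD, n = 4) to 6.31 ± 0.21 (SD, n = 3). Efflux transporters were lower in 9 of 9, with a median of -1.06, and Abcb1b at -1.25 (SE 0.44) and Abcc3 at -1.30 (SE 0.48) also passed over the list alone. The DNA repair genes Rad51c at 1.47 (SE 0.30) and Brca1 at 1.22 (SE 0.29) were higher over the homologous recombination list alone and missed the threshold over all genes, with adjusted p of 0.0646 and 0.0986. The list's median was 0.42, with 26 of 30 positive. Macrophage markers were lower, with a median of -1.27 and 7 genes past the threshold over the list alone, including C1qc at -1.37 (SE 0.44) and the growth factor receptor Csf1r at -1.27 (SE 0.43), and 0 over all genes. Cytotoxic effector genes were lower in 11 of 11, with a median of -2.20, and the granzyme Gzmc at -3.27 (SE 0.91) was the 1 member past the threshold over the list alone. NK cell markers had a median of -1.37 (adjusted p = 0.0019; adjusted p = 0.66 with an estimated correlation), and were not called without MDA594_control 1 (-0.96); the median was -2.31 without MDA594_control 2.

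In that comparison adjusted p was 5.46e-05 for efflux by the camera test of limma (adjusted p = 0.582 with an estimated correlation). It was 8.42e-07 for homologous recombination and for macrophage markers and 8.98e-06 for cytotoxic genes (adjusted p = 0.66 with an estimated correlation for each). Of 35 lists, 7 were higher and 15 lower, 0 with an estimated correlation and 0 with fry. Within 1 library-name series the efflux median was -1.12, the homologous recombination median 0.59 and the macrophage median -0.77. OR1_control 3 is the only untreated OR1 library there. The 7 macrophage genes became 0 without MDA594_control 1, MDA594_control 3, OR1_control 1 or OR1_control 2. The 3 efflux genes became 1 without MDA594_control 3, MDA594_control 4, OR1_control 2 or OR1_control 3. Muscle markers were higher in untreated OR1 (median 3.69, adjusted p = 1.82e-04; adjusted p = 0.675 with an estimated correlation), and 0 of them passed over the list alone. They were not called within 1 library-name series (2.54). Mitochondrially encoded genes were lower in 13 of 13, with a median of -1.13 (adjusted p = 1.87e-06; adjusted p = 0.66 with an estimated correlation), and were not called with the title number in the model (-0.78). Fibroblast markers had a median of -0.63 and endothelial markers of -0.46 (adjusted p = 0.0388 for each; adjusted p = 0.675 with an estimated correlation), and red cell genes of 1.45 (adjusted p = 0.00138; adjusted p = 0.66 with an estimated correlation). The latter 3 were not called within 1 library-name series (-0.13, -0.61 and 0.41). Without MDA594_control 1 all 3 lost the call (-0.62, -0.35 and 0.96). Fibroblast and endothelial markers lost it without MDA594_control 3 (-0.36 and -0.27) or OR1_control 1 (-0.56 and -0.18), and endothelial markers without OR1_control 3 (-0.57). The endothelial median was -0.71 without MDA594_control 2 and -0.73 without OR1_control 2. Efflux, macrophage, homologous recombination, muscle, red cell and mitochondrial lists moved the other way with olaparib in OR1. That response uses the same untreated OR1 libraries, so these opposite changes are not independent.

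Over all genes, 6 were higher and 12 lower in untreated OR1. The homeobox factors Onecut2 (ENSMUSG00000045991.20) at 4.01 (SE 0.66, adjusted p = 0.0293) and Cux2 at 3.49 (SE 0.61, adjusted p = 0.0311) were higher, as was the zinc finger factor Fezf1 (ENSMUSG00000029697.7) at 2.79 (SE 0.46, adjusted p = 0.0293). Onecut2 was 0.55 ± 1.09 (SD, n = 4) in MDA594 and 4.69 ± 0.10 (SD, n = 3) in OR1. Rnf157, Prkd1 and Cdr2l were higher by 0.89 to 2.16. The collagen Col11a2 (ENSMUSG00000024330.18) was lower at -4.40 (SE 0.66, adjusted p = 0.0152), from 8.14 ± 0.08 (SD, n = 4) to 3.73 ± 0.16 (SD, n = 3). Clca3a1, the complement gene C4b, Tesc, Fndc1, the B cell adaptor Blnk and the prostaglandin transporter Slco2a1 were lower by -3.83 to -1.95. At the unadjusted threshold there were 2216 genes against 816 by chance, and voom called 1 higher and 1 lower. The counts were 93 and 105 without MDA594_control 1, 3 and 7 without MDA594_control 2, 1 and 5 without OR1_control 1, and 0 and 0 without OR1_control 3. They were 17 and 31 with the library-name series in the model and 0 and 0 with the title number. No title number holds untreated libraries of both lines, so the latter fit links them only through treated OR1_olaparib 1 and MDA594_control 1. Within 1 series OR1_control 3 was the only untreated OR1 library, so counts there are not read.

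The fifth comparison asked how untreated OR2 differed from untreated MDA594. The largest falls were in imprinted genes, which are expressed from 1 parental copy. Snhg14 (ENSMUSG00000100826.8), a long noncoding RNA that carries small nucleolar RNAs, fell by 7.77 (SE 0.37, adjusted p = 2.20e-09), and Snrpn (ENSMUSG00000102252.6), a splicing protein gene of the same locus, fell by 6.84 (SE 0.35, adjusted p = 4.00e-09). Kcnq1ot1 (ENSMUSG00000101609.5), a noncoding RNA antisense to Kcnq1, fell by 5.79 (SE 0.67, adjusted p = 5.21e-04), and the receptor gene Igf2r (ENSMUSG00000023830.15) fell by 5.30 (SE 0.99, adjusted p = 0.0351). Snrpn had 9 and 19 reads in untreated OR2 and 754 to 1776 in untreated MDA594. Treated OR2 had 21, 34 and 25 Snrpn reads. Snhg14 had 11 and 14 reads in untreated OR2 and 1709 to 2899 in untreated MDA594. Igf2r had 1069 and 2073 reads in untreated OR2, and 62845, 2763 and 1329 in the 3 treated OR2 libraries. The calls of Snhg14, Snrpn and Kcnq1ot1 were lost in 0 of 22 alternatives, with adjusted p up to 0.0469, and that of Igf2r in 8 of 22, with adjusted p from 4.52e-06 to 0.637. Igf2r was not called without MDA594_control 2 (-5.33), and its change was -4.88 without OR2_control 1. With the title number in the model it changed by -0.49. That fit links the lines only through MDA594_control 2 and treated OR2_olaparib 1, the library with 62845 Igf2r reads. Snrpn and Snhg14 overlap, so they are not independent measurements.

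**Figure D3:**
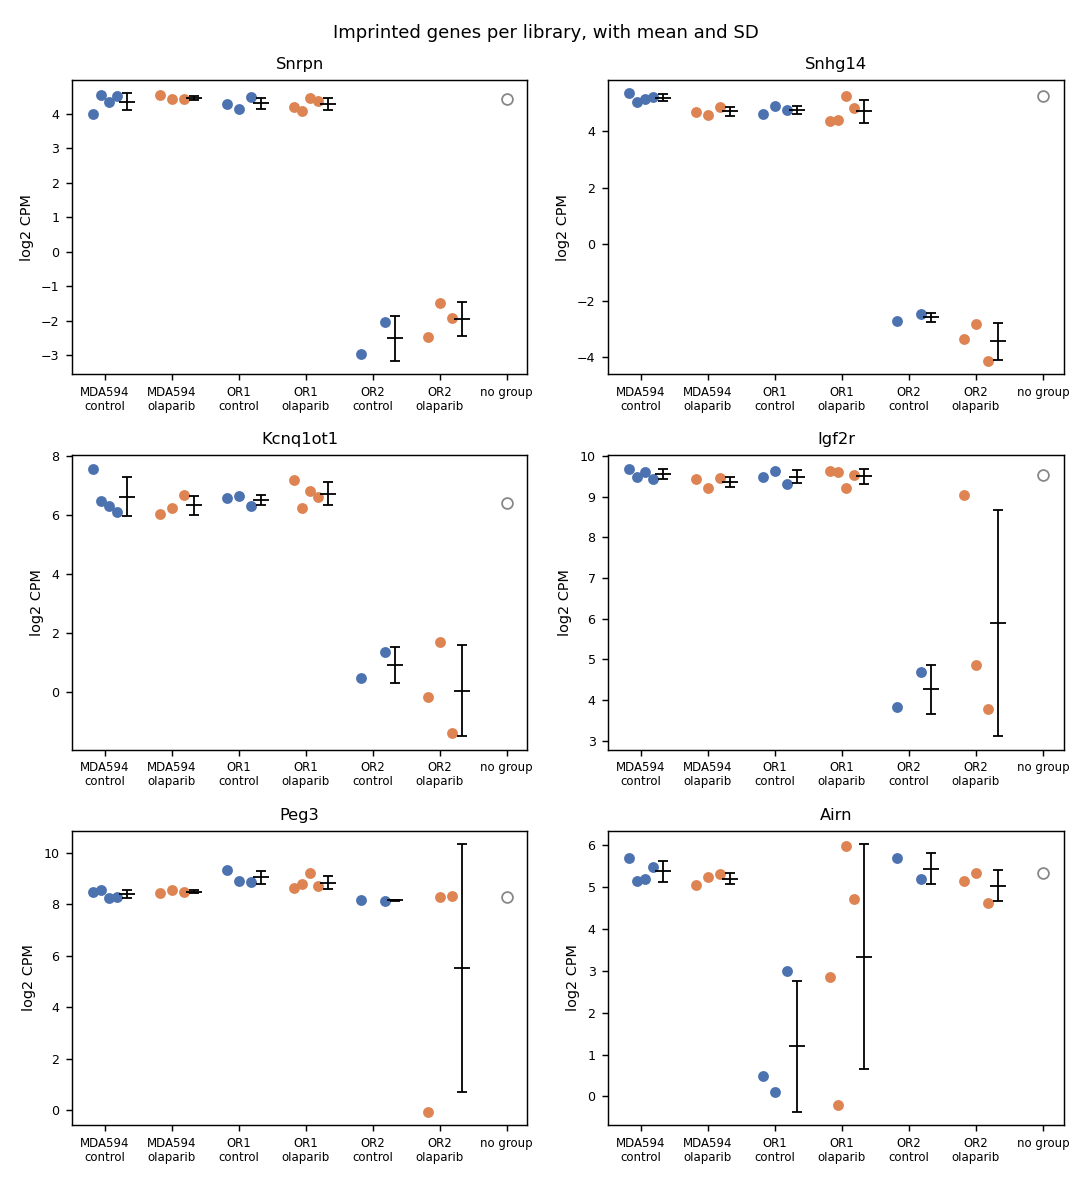
Log2 CPM of imprinted genes in each library (vertical axis) by tumour line and treatment (horizontal axis); points are libraries, black bars are the mean and SD, and the open grey point is the library with no group. Snrpn was -2.51 ± 0.66 (SD, n = 2) in untreated OR2 and 4.35 ± 0.25 (SD, n = 4) in untreated MDA594, and Igf2r was 9.05 in OR2_olaparib 1.

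Among 21 genes that were higher in untreated OR2, Fezf1 had a change of 4.38 (SE 0.55, adjusted p = 0.00128), from -1.47 ± 0.76 (SD, n = 4) to 3.01 ± 0.22 (SD, n = 2). The scaffold protein gene Card14 was higher by 4.08 (SE 0.79), the adhesion gene Ncam1 by 2.08 (SE 0.41), and Wfdc3, Rnd3 and Gas1 by 1.89 to 2.81. Xbp1, a transcription factor of the unfolded protein response named outside the rule, was higher by 1.31 (SE 0.24, adjusted p = 0.0351). That list was not called by the camera test (median 0.04, adjusted p = 0.395), with 9 genes positive and 9 negative. Fads2b, of the fatty acid desaturase family, had 390 and 573 reads in untreated OR2 and 0, 0, 2 and 0 in untreated MDA594, while the 3 treated OR2 libraries had 10, 63 and 39. The phosphate transporter gene Slc34a2 had 283 and 135 reads in untreated OR2 and 4, 2, 5 and 7 in untreated MDA594. Of 14 genes that were lower, Morn4, Aif1l, Dst and the collagen Col9a3 were lower by -2.37 to -1.84. At the unadjusted threshold there were 1730 genes against 816 by chance, and voom called 31 higher and 8 lower. The counts were 53 and 43 without MDA594_control 1, 40 and 26 without MDA594_control 3, 39 and 26 without MDA594_control 4, 1 and 4 without OR2_control 1, and 97 and 126 without OR2_control 2. They were 2217 and 1813 within 1 library-name series, and 93 and 108 with the title number in the model, where Fezf1 was not called. Within 1 series each untreated group holds 1 code. The title number links these lines only through treated OR2_olaparib 1 and MDA594_control 2.

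Interferon-induced genes were higher in untreated OR2 than in untreated MDA594 in 36 of 37, with a median of 0.94 and 0 past the threshold over the list alone or over all genes. Class II genes were lower in 11 of 11, with a median of -2.76; the class II transactivator Ciita was at -3.14 (SE 0.88) and Cd74 at -2.90 (SE 0.94). Neutrophil markers had a median of 1.87, led by the chemokine receptor Cxcr2 at 2.79 (SE 0.76) and the growth factor receptor Csf3r at 2.42 (SE 0.67). Hypoxia genes had a median of 0.73, with Egln3, an oxygen-sensing enzyme, at 1.23 (SE 0.31), and milk genes a median of 1.11, with Csn2 at 5.25 (SE 1.56). T cell markers had a median of -1.75 and 0 past the threshold over the list alone. Class II, T cell, neutrophil, hypoxia, milk and red cell lists moved the other way with olaparib in OR2. That comparison uses the same untreated OR2 libraries, so these opposite changes are not independent. Red cell genes had a median of 2.18 (adjusted p = 5.22e-04; adjusted p = 0.725 with an estimated correlation) and mitochondrially encoded genes of -0.75 (adjusted p = 0.00751; adjusted p = 0.768 with an estimated correlation). Neither was called within 1 library-name series (1.39 and -0.85) or without OR2_control 2 (1.65 and -0.37), both changed sign with the title number in the model (-0.81 and 0.82), and mitochondrial genes were not called without MDA594_control 1 (-0.66) or with quantile normalisation (-0.25). By the camera test of limma, adjusted p was 1.38e-08 for interferon (adjusted p = 0.725 with an estimated correlation) and 6.80e-05 for T cell markers (adjusted p = 0.768 with an estimated correlation). It was 1.29e-07 for class II, 3.47e-06 for neutrophils, 1.27e-06 for hypoxia and 6.69e-04 for milk genes (adjusted p = 0.643 with an estimated correlation for each). Of 35 lists, 9 were higher and 5 lower, 0 with an estimated correlation and 0 with fry. Within 1 library-name series the interferon median was 1.17 and the class II median -2.73; neutrophil markers and milk genes (1.57) were not called there. With the title number in the model, class II at -1.21, neutrophil markers at 0.86 and T cell markers at -0.83 were not called. Nor were milk genes at 1.56 or hypoxia genes at 0.32. No title number holds untreated libraries of both lines, so that fit links them only through treated OR2_olaparib 1 and MDA594_control 2. These values, and the changes of sign above, rest on that link. The 7 class II genes past the threshold over the list alone, of which 0 passed over all genes, became 0 without OR2_control 1, and the milk list was not called without OR2_control 2 (0.90). Without MDA594_control 1 the class II median was -1.76 and the T cell median -1.02, and without OR2_control 1 the T cell median was -1.08 and the hypoxia median 0.48. Abcg2 was at -1.05 (SE 0.35) in untreated OR2, with an adjusted p of 0.233 over all genes.

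Fezf1 was the 1 gene called in the same direction in both untreated resistant tumours against untreated MDA594. Both comparisons use the same MDA594 controls, which correlates them: across genes, which are not independent replicates, the correlation of their changes was 0.385, and 0.347 in simulations with unchanged groups. Their covariance was 0.201, against 0.0876 in those simulations. The mean overlap in 20 such simulations was 0. With no group changed, hardly any gene can be called in either comparison, so this value was nearly fixed in advance. It does not bear on the 1 shared gene. The simulated fits also moderated variances without a mean trend. The number of shared genes was 16 without MDA594_control 1, 2 without MDA594_control 2 or MDA594_control 4, and 0 without OR1_control 1, OR1_control 3, OR2_control 1 or OR2_control 2.

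The last comparisons tested whether the resistant tumours responded to olaparib differently from MDA594. In OR1, mitotic and S phase genes had a response lower than in MDA594 in 30 of 30, with a median difference of -0.69. Rrm2, which makes deoxynucleotides, differed by -1.36 (SE 0.31), the helicase subunit Mcm5 by -1.23 (SE 0.31) and Pcna by -0.996 (SE 0.27). Of the 30, 13 passed over the list alone and 0 over all genes. Homologous recombination genes had a median difference of -0.51, and neutrophil markers of 2.30. The interferon list differed by -0.38 with an adjusted p of 0.0471 (adjusted p = 0.929 with an estimated correlation), and was not called without MDA594_control 2 (-0.10), MDA594_olaparib 1 (-0.03), OR1_control 1 (-0.32), OR1_control 2 (-0.38), OR1_olaparib 3 (-0.18) or OR1_olaparib 4 (-0.28). It was larger without MDA594_control 1 (-0.86), MDA594_olaparib 2 (-0.59), MDA594_olaparib 3 (-0.63) or OR1_olaparib 1 (-0.67), within 1 library-name series (-0.97) and with the title number in the model (-1.31, adjusted p = 2.16e-09). The camera test of limma gave 7.56e-21 for mitotic genes, 1.47e-07 for homologous recombination and 1.87e-07 for neutrophil markers (adjusted p = 0.429 with an estimated correlation for each). Within 1 library-name series the mitotic difference was -0.92. The 13 genes became 7 without MDA594_olaparib 2, OR1_control 1 or OR1_olaparib 3, 3 without MDA594_olaparib 3, 8 without OR1_control 3, 6 without OR1_olaparib 2 and 20 without OR1_control 2. Of 35 lists, 3 were higher and 8 lower, 0 with an estimated correlation and 0 with fry. Over all genes limma called 0 higher and 0 lower, with 1197 under the unadjusted threshold against 816 by chance, and voom called 0. The counts were 141 and 216 within 1 library-name series and 497 and 681 with the title number in the model.

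In OR2, interferon-induced genes had a response lower than in MDA594 in 37 of 37, with a median difference of -2.15. The interferon score was 3.94 ± 0.06 (SD, n = 2) in untreated OR2 and 3.67 ± 0.60 (SD, n = 3) in treated OR2. In MDA594 it was 2.86 ± 0.77 (SD, n = 4) untreated and 4.75 ± 0.72 (SD, n = 3) treated. Both untreated OR2 libraries share a host code. A high level in that 1 animal can thus not be told apart from a different response of the line. Isg15 differed by -3.09 (SE 0.82) and Cxcl10 by -2.74 (SE 0.84), with adjusted p of 0.585 and 0.644 over all genes, and 0 of 37 passed over the list alone, against 29 at the unadjusted threshold. Chemokines had a median difference of -1.09, macrophage markers of -0.82 and nucleic acid sensing genes of -0.32. Basal and keratinocyte genes had a median of -1.54, with the cell cycle regulator Sfn at -1.63 (SE 0.45) past the threshold over the list alone. The camera test of limma gave 8.34e-28 for interferon, 0.00211 for nucleic acid sensing and 9.07e-04 for basal genes (adjusted p = 0.442 with an estimated correlation for each). It gave 0.00387 for chemokines (adjusted p = 0.555 with an estimated correlation) and 0.0033 for macrophage markers (adjusted p = 0.696 with an estimated correlation). Neither of these was called without OR2_control 2 (-0.53 and -0.61) or OR2_olaparib 1 (-0.48 and -0.36). The chemokine difference was -0.72 without MDA594_control 2, that of macrophage markers -1.41 without OR2_olaparib 2, and that of nucleic acid sensing -0.21 without MDA594_olaparib 1. For interferon the difference was -2.60 within 1 library-name series and -2.75 with the title number in the model, and for macrophage markers it was -0.23 and -0.21 and not called. Of 35 lists, 0 were higher and 15 lower, 0 with an estimated correlation and 0 with fry. Over all genes limma called 0 higher and 0 lower, with 1006 under the unadjusted threshold against 816 by chance, and voom called 0. The counts were 20 and 10 without OR2_control 2, 0 and 3 without OR2_olaparib 2, 358 and 605 within 1 library-name series and 94 and 208 with the title number in the model.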

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

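Of the tests in this part, those of a lower tumour share, of the clock genes, of each single imprinted region, of reads assigned to partner genes and of the series for the imprinted genes were chosen only after the result was seen.

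Interferon-induced genes were higher with olaparib in MDA594, with a list median of 1.82. A smaller share of tumour cells would raise all host cell types alike, and 4 of 5 host lists were higher: medians were 0.813 for fibroblasts, 0.719 for endothelium, 1.11 for macrophages and 1.45 for T cells, against -0.538 for neutrophils. Those of fibroblasts and endothelium were 0.295 and 0.365 without MDA594_olaparib 3 and 0.111 and 0.129 with the title number in the model, and neither was called there. T cell markers were at 0.605 without MDA594_control 2 and neutrophil markers at -0.294 without MDA594_control 3, and were not called there either. The most distant of these 10 pairs, T cells and neutrophils, differed by 2.23 (SE 0.826), within the bound of 2.79 for the most extreme pair, so a smaller tumour share stays open. The series of the library names is argued against by a median of 2.11 with the series in the model. More immune cells in treated tumours may account for part of it: the score difference of 1.8 (SE 0.539) became 1.2 (SE 0.582) with an immune marker score as a covariate, and its 95% interval from -0.0694 to 2.47 includes 0. The bound written beforehand, 2 standard errors (1.16), was passed, but it is too narrow for 12 residual degrees of freedom, so this stays open, as does a direct effect of olaparib on the tumour cells, which was not tested.

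Clock-controlled genes were lower with olaparib in MDA594. Dbp and Rora were called, and over 11 clock genes, listed after Dbp had been seen, the mean change was -0.963 (SE 0.174), with 10 lower at an unadjusted p under 0.05 and 1 called over all genes. Host muscle in MDA594_olaparib 3 is argued against, since the mean was -0.923 (SE 0.214) without that library. Tissue taken at another time of day could give such a shift and would move genes of the opposite phase the other way; these changed by -0.338 (SE 0.195, 5 genes), which decides nothing, and collection times are not in the labels. The mean change was 0.219 (SE 0.174) in OR1 and -0.62 (SE 0.211) in OR2, and an effect of olaparib itself was not tested.

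Snhg14, Snrpn, Kcnq1ot1 and Igf2r were far lower in untreated OR2 than in untreated MDA594, with a median change of -6.32; Snrpn had 9 and 19 reads there, and Igf2r still had 1069 and 2073. With the library-name series in the model it was -6.29, which argues against the series for the set. MDA594_control 3 and MDA594_control 4, of the same series as untreated OR2, had 57274 and 54046 Igf2r reads. This argues against the series for the fall of Igf2r against MDA594 too, although those libraries share a host code. OR2_olaparib 1, which kept a high Igf2r, is the only OR2 library of its series and of its title number. The difference in Igf2r between that library and the other OR2 libraries can thus not be parted from series or title number. Loss of wide chromosome regions could lower the neighbours. Over 60 neighbouring genes the median was 0.0555 (SE 0.193), which argues against such a fall around every gene of the set. It pools regions that moved in opposite directions. The SE takes neighbouring genes as independent, although both untreated OR2 libraries share a host code. A change of the parental copies that leaves the neighbours at their level was not tested. Around Kcnq1ot1 the median was 0.514 (SE 0.269), against a fall there. Around Snrpn and Snhg14 it was 0.113 (SE 0.425), too uncertain to decide, and around Igf2r it was -0.72 (SE 0.171) with 17 of 20 below 0, so a regional loss may contribute there. Reads assigned to a partner gene would leave the summed CPM of both unchanged. It changed by -3.64 (SE 0.81) for Igf2r with its antisense Airn and -5.01 (SE 0.628) for Kcnq1ot1 with Kcnq1, which argues against that. For Snrpn with Snhg14 it was -7.36 (SE 0.299). Each of them fell by itself, so their sum had to fall and adds nothing to their single changes. With Ube3a, antisense to Snhg14, added to the last pair it was -0.365 (SE 0.12), against a transfer of all their reads. Small deletions and a change of imprint stay open, as does any link to resistance, which was not tested.

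Other splits of the libraries were compared for 4 counts. For olaparib in MDA594, 2 of 35 splits gave at least as many genes (20 in the real split, 146 in the highest other), so chance cannot be excluded. The split with 146 set MDA594_control 2, 3 and 4 against MDA594_control 1 with the treated libraries, which points to a structure around MDA594_control 1. Of the 35 splits, 28 part libraries that share a host code, and each of these called 0 genes. The 7 that keep codes whole, of which 2 gave as many, are too few for a share under 0.05. For untreated OR1 against MDA594, 2 of 35 splits gave as many (18 in the real split, 20 in the highest other, which put MDA594_control 1 with the OR1 controls), and chance cannot be excluded; again 28 part a code and called 0, and 2 of the 7 others gave as many. For olaparib in OR1 and for the difference between the OR1 and MDA594 responses the real split called 0 genes, so all 35 and all 100 splits gave as many by construction, and these counts decide nothing. The highest other splits gave 13 and 319.

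Single libraries stood far from the rest of their group in 9 of 162 sets of values tested, against 8.1 expected at 1 in 20 by chance. The critical value of this outlier test (Dixon) was that for 4 libraries, the size of only untreated MDA594 and treated OR1. Smaller groups are not in this count, so the muscle markers of MDA594_olaparib 3 could not be flagged. The score of cytotoxic effector genes was 1.37 in MDA594_control 3, and that of glutathione and NRF2 targets was 4.19 in MDA594_control 1. Log2 CPM were 4.72 for Cxcl10 in MDA594_control 1, 4.43 for Cdr2l in MDA594_control 4 and 8.26 for Col11a2 in MDA594_control 2. They were 4.28 for Clec7a and 1.39 for Fads2b in OR1_olaparib 4, 2.18 for Wfdc3 in OR1_olaparib 1 and 10.1 for Col9a3 in OR1_olaparib 3.

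The response to olaparib differed between OR1 and MDA594 in 11 lists by an interaction test with the preset correlation, and in 0 with an estimated correlation. The median differences were -0.381 for interferon, 2.30 for neutrophil markers, -0.509 for homologous recombination, -0.263 for 53BP1 and end joining, -0.364 for PARP and base excision factors and -0.685 for mitosis and S phase. They were -6.08 for muscle, 0.509 for hypoxia, -0.448 for the unfolded protein response, -2.11 for red cell and platelet genes and 1.28 for mitochondrially encoded genes. The muscle difference rests largely on MDA594_olaparib 3 and was -2.72 without it. The last 5 were not called within 1 library-name series (-2.58, -0.0728, -0.351, -0.175 and 0.851). Red cell genes were not called without MDA594_control 1 (-1.44), OR1_control 2 (-1.82) or OR1_olaparib 1 (-1.61). The interferon call was lost without MDA594_control 2 (-0.0992), MDA594_olaparib 1 (-0.033), OR1_control 1 (-0.317), OR1_control 2 (-0.377), OR1_olaparib 3 (-0.177) or OR1_olaparib 4 (-0.281). Its difference was larger without MDA594_control 1 (-0.862), MDA594_olaparib 2 (-0.588), MDA594_olaparib 3 (-0.63) or OR1_olaparib 1 (-0.668).

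Between OR2 and MDA594 the response differed in 15 lists by the same test, and in 0 with an estimated correlation. All these differences subtract untreated OR2, whose 2 libraries share a host code. The median differences were -2.15 for interferon, -0.324 for nucleic acid sensing, -1.09 for chemokines, -0.475 for NK cell ligands, -0.82 for macrophage markers, -0.97 for immune checkpoints and -0.763 for mesenchymal genes. They were -1.54 for basal genes, -0.812 for fibroblast markers, -0.838 for endothelial markers, -5.71 for muscle and -0.915 for milk genes. For the unfolded protein response it was -0.315, for NF-kB genes -0.665 and for red cell and platelet genes -3.12. Of these 15, muscle was not called without MDA594_olaparib 3 (-1.29), nor were fibroblast (-0.383) and endothelial markers (-0.448). Without MDA594_control 1 fibroblast markers (-0.896) lost the call, without MDA594_control 2 fibroblast markers (-0.824), NK cell ligands (-0.523) and checkpoints (-0.891), and without MDA594_control 4 fibroblast markers (-0.635) and NK cell ligands (-0.435). Without MDA594_olaparib 1 NK cell ligands (-0.499) and checkpoints (-0.596) lost it. Without OR2_control 1 it was NK cell ligands (-0.17), the unfolded protein response (-0.259) and NF-kB genes (-0.494). Without OR2_control 2 it was chemokines (-0.528), macrophages (-0.608), checkpoints (-1.13), mesenchymal genes (-0.632), fibroblasts (-0.675), endothelium (-0.169), milk genes (-0.792) and red cell genes (-2.6). Without OR2_olaparib 1 it was chemokines (-0.48), NK cell ligands (-0.467), macrophages (-0.357), checkpoints (-0.794), mesenchymal genes (-0.567), fibroblasts (-0.484), endothelium (-0.399), the unfolded protein response (-0.274) and NF-kB genes (-0.371). Without OR2_olaparib 3 it was NK cell ligands (-0.483), fibroblasts (-0.481) and milk genes (-0.372). Calls that were kept moved by over 1.5 times in some lists. These were chemokines without MDA594_control 2 (-0.719), nucleic acid sensing without MDA594_olaparib 1 (-0.213), and fibroblasts (-1.32) and endothelium (-1.53) without OR2_control 1. They were also NK cell ligands without OR2_control 2 (-0.765), the unfolded protein response without OR2_olaparib 3 (-0.488), and macrophages (-1.41), mesenchymal genes (-1.23), fibroblasts (-1.54), endothelium (-1.4) and milk genes (-1.38) without OR2_olaparib 2.

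The library with no group scored above all 4 MDA594 controls in 16 of 35 lists, and by more than 1 SD of the controls in 5 of them. Those 5 were mitosis and S phase at 6.82 (controls up to 6.54), muscle markers at 2.41 (up to -2.88), the unfolded protein response at 6.27 (up to 5.98), 53BP1 and end joining at 4.39 (up to 4.29) and adipocyte markers at 1.85 (up to 1.16). The others were interferon at 4.14, chemokines at 3.17, NK cell markers at 2.19, T cell markers at 1.81, dendritic cell markers at 2.42, class I at 8.42 and class II at 6.23. Immune checkpoints were at 3.06, homologous recombination at 5.03, PARP and base excision factors at 5.45, and glutathione and NRF2 targets at 4.60.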

How the results depend on the processing

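Voom weights and the fit without the MDA594 control code that stood apart were chosen only after the data had been seen. Counts are genes higher and lower; where a setting is not named for a comparison, its counts stayed within 1.5 times. The cause was not tested unless stated. Removing the filter moved no count by that much. For olaparib in MDA594 (9 and 11) the counts were 25 higher with 1 CPM added, 18 and 39 with quantile normalisation, 1 and 7 with libraries shifted to one median, 519 and 505 without the code block, and 54 and 57 with the series as covariate. They were 2857 and 2363 in only one series, 1764 and 1359 with the title number, and 1 and 2 without the control code apart. They were 0 and 0 with the mean per code, only the groups compared, no trend, robust moderation, a threshold of 0.01 or voom. For olaparib in OR1 (0 and 0) they were 143 and 5 with only the groups compared. For olaparib in OR2 (0 and 0) they were 1 lower with 1 CPM added, 6 and 7 without the code block, 146 and 217 in only one series and 35 and 40 with the title number; the fit with only the groups compared could not be made there. For untreated OR1 (6 and 12) they were 233 and 291 without the code block, 19 lower with the mean per code, 17 and 31 with the series as covariate, 917 and 528 in only one series, 6 lower without trend and 1 and 1 with voom. They were 0 and 0 with the title number, a threshold of 0.01 and without the control code apart. For untreated OR2 (21 and 14) they were 13 higher with a mean above 2, 52 and 23 with 1 CPM added, 37 and 22 with quantile normalisation, 9 lower with shifted libraries, 298 and 244 without the code block, and 5 and 8 with the mean per code. They were 2217 and 1813 in only one series, 93 and 108 with the title number, 1 and 6 with only the groups compared, 9 lower without trend, 1 and 4 at a threshold of 0.01 and 8 lower with voom. For the OR1 difference (0 and 0) they were 141 and 216 in only one series, 497 and 681 with the title number and 1 higher without the control code apart. For the OR2 difference (0 and 0) they were 358 and 605 in only one series and 94 and 208 with the title number. Genes shared by both untreated contrasts (1) numbered 2 with quantile normalisation, 68 without the code block and 1051 in only one series. They numbered 0 with a mean above 2, 1 CPM added, the mean per code, the title number, only the groups compared, a threshold of 0.01, voom, without the control code apart and in the lowest split of the MDA594 controls. In only one series and with the title number the estimated correlation between libraries of a code was -0.298 and -0.127; a negative value narrows the standard errors by construction, and how much of the counts comes from that and how much from the changed libraries or model was not separated. Leaving out the code block treats libraries of 1 host as independent, which raised false calls in simulations that had this correlation built in. A threshold of 0.01 calls fewer genes by construction.

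Without 1 library at a time, the counts higher and lower ranged from 0 to 251 and 0 to 138 for olaparib in MDA594, 0 to 1 and 0 to 0 in OR1, and 0 to 64 and 0 to 38 in OR2. They ranged from 0 to 93 and 0 to 105 for untreated OR1, 1 to 97 and 4 to 126 for untreated OR2, 0 to 0 and 0 to 0 for the OR1 difference, 0 to 20 and 0 to 10 for the OR2 difference, and 0 to 16 for shared genes. A group left with 1 library was assumed to vary like the others. Of 16 named genes called for olaparib in MDA594, each lost its call in 10 to 14 of 22 to 23 alternatives; for 14 in untreated OR1 it was 5 to 16, and for 16 in untreated OR2 0 to 10 of 21 to 22, and 0 reversed. Of 125 list calls, 0 held with an estimated correlation and 5 with fry. In refits with the preset correlation, the calls lost in none were 10 of 23 for olaparib in MDA594, 17 of 30 in OR1, 4 of 10 in OR2, 6 of 22 for untreated OR1, 1 of 14 for untreated OR2, 5 of 11 for the OR1 difference and 3 of 15 for the OR2 difference. Lists that reversed were muscle in MDA594 (-0.369 with the title number, -0.376 to 4.97 without 1 library, lowest without MDA594_olaparib 3), milk in OR1 (test reversed, median 0.0776 in only one series) and interferon in untreated OR1 (-0.646 to 0.106 without 1 library, highest without MDA594_control 1). In untreated OR2 with the title number the sign changed for epithelial (-0.278), immediate early (-0.461), NF-kB (-0.336), red cell (-0.809) and mitochondrial genes (0.822). No title number holds untreated libraries of both OR2 and MDA594, so that fit links these lines only through a treated OR2 library. Those sign changes rest on that link and are not read as reversals of the untreated comparison. The OR1 difference of red cell genes (test reversed, -0.175 in only one series) and the OR2 differences of fibroblast (test reversed at -0.174 in only one series, 0.028 with the title number) and endothelial markers (0.232 with the title number) reversed too. Depth was not varied: the 20 libraries had 36.8 to 118 M reads, and genes with few reads, such as Fads2b, are given as reads.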

Other observations

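The values in this part were chosen only after the data had been seen. Of 39 imprinted genes written down after the first imprinted genes had been seen, 30 were tested; 4 were called in untreated OR2 and 0 in untreated OR1. Mkrn3 was at -3.74 (adjusted p = 0.128) and Igf2 at -2.70 (adjusted p = 0.361) in untreated OR2. These were the lowest of the genes not called, which went both ways. H19 was at 1.59, Slc22a18 at 1.07 and Ndn at 0.488, none of them called. Airn, antisense to Igf2r, had 33, 48 and 73 reads in OR1_olaparib 2, OR1_control 2 and OR1_control 1, and 3172 in OR1_olaparib 3, and its untreated OR1 change of -3.97 was not called (adjusted p = 0.221). Peg3 had 114 reads in OR2_olaparib 1 and 21510 to 30999 in the other 4 OR2 libraries. Igf2r was at 9.05 in that same library and at 3.78 to 4.85 in the other 4 OR2 libraries. OR2_olaparib 1 also differs from those 4 in library-name series and title number.

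The library with no group had Pearson correlations across genes, which are not independent replicates, of 0.974 to 0.977 with treated MDA594 libraries and 0.945 to 0.96 with untreated ones. Its log2 CPM were 5.66 for Cxcl10 and 3.22 for Isg15, against 5.59 to 6.48 and 3.53 to 4.78 in treated MDA594 and 2.34 to 4.72 and 0.68 to 2.50 in untreated MDA594. It was not moved to a group. Pairs of libraries that share a code correlated at 0.956 to 0.986 (5 pairs), and other pairs of a group at 0.927 to 0.971 (17 pairs). Muscle transcripts Ckm and Acta1 were at 6.01 and 8.81 in MDA594_olaparib 3, and at 2.16 and 5.32 in the library with no group. The antibody light chain gene Igkc was at 6.96 in MDA594_control 1.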
